A study of Mus musculus with 14 samples.

How the data were processed

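The samples were sorted Confetti-positive cells from the anterior prostate of 3-month-old mice, 4 weeks after tamoxifen. There were 14 samples: 5 bulk libraries of dominant clones, 7 bulk libraries of minor clones, and 1 single-cell library of each kind (10x Genomics chemistry). Groups and replicate numbers came from the labels, which state no pairing, litter, colour or batch for a library.

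For the bulk libraries, the deposited values are TPM per gene symbol, and each library sums to just under the nominal TPM total. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3, Cell Ranger 3.0.2 and the genome build mm10 without a role or order. The quantifier behind the TPM values and the annotation are not given in the sources used here. The table has 35251 gene entries, of which 10211 are 0 in every library, 26 carry symbols turned into dates and 2 symbols occur more than once. For the single-cell libraries, the deposited values are UMI counts per gene and barcode, made with Cell Ranger 3.0.2 per the file headers, with barcodes already filtered as deposited. Coordinates were taken from GENCODE M21 (GRCm38).

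Bulk values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend, two-sided), for the 12851 genes with at least 1 TPM in at least 5 libraries. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05 on the adjusted p. Of 38 gene lists (22 functional and 16 of cell types), 34 had at least 5 measured members and were tested. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested with camera (preset correlation between genes of 0.01), with camera and an estimated correlation, and with fry, and the mean of each list per library was compared by a two-sided exact permutation test over the 792 splits of 12 libraries into 5 and 7. The same permutation test was applied to 4 library quality measures. The fit was tested on simulated data: of 100 genes given an absolute log2 change of 1 it called 45%, of 100 given a change of 2 it called 84%, and it made 8 false calls. The simulation shuffled residuals within each gene, which removes correlation between genes, so its false calls do not describe the real libraries.

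Named genes are Pten, Kras and Nkx3-1; the 12 genes per direction with the largest log2 fold change past the threshold; for each list up to 4 members with the smallest p and those past the threshold; the 12 single-cell genes per direction with the largest ratio among genes with at least 100 UMIs in total and 50 CPM in a library; and the markers that named clusters. Predicted genes, ribosomal and mitochondrial genes were counted and not named.

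Single-cell data were processed in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The libraries had been counted against gene sets of different size, so the 30726 shared genes were used. Shared genes that overlap an exon of, or share at least 60 nt at 97% identity over the last 500 nt of a transcript with, a gene counted in only 1 library were marked as open to an effect of the gene sets, and they were left out of the clustering. Cells with at least 500 genes, 1000 UMIs and under 20% mitochondrial UMIs were kept: 8083 dominant cells (median 5615 UMIs and 2087 genes) and 6078 minor cells (median 7043 UMIs and 2205 genes). Their median mitochondrial share was 0.996 and 4.42% over the shared genes, on which the filter acted. Over all genes counted in each library it was 3.51 and 4.42%, the dominant library having 37 mitochondrial genes in its gene set and the minor library 13, so these shares are not a like measure of cell quality. Doublet scoring with scrublet called 0 doublets in both libraries, so doublets were not removed. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, and were named where at least 3 markers of a class were among their 30 leading genes. A cluster with smooth muscle markers was kept in the epithelial class because over 50% of its cells had Epcam, Krt8 and Krt18, a rule settled after the cluster had been seen.

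UMIs were summed over the epithelial cells of each library (51263020 and 48196696 UMIs) and expressed as CPM. Ratios are dominant over minor, over 12087 genes with at least 100 UMIs. The median ratio of each list was placed among 10000 random lists of the same size and matched expression. Leukocyte genes are those at least 8-fold higher, and epithelial genes those at least 3-fold higher, in 1 of these classes of the single-cell libraries than in the other. Alternatives covered the pseudocount, the filter, the scaling, library weights, each left-out library, the replicate number as a block, cell filters, clustering and the CPM total. Scaling to epithelial genes, leaving out leukocyte genes or the libraries with over 5000 TPM of seminal vesicle genes, and those that concern the gene sets, doublet scores, the cluster with smooth muscle markers and the centring of directions were chosen after seeing the data.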

Results

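RNA was measured in sorted prostate cells of mice in which a tamoxifen-inducible Cre recombinase at the Nkx3-1 locus deletes the tumour suppressor Pten and switches on an oncogenic Kras allele, while a Confetti reporter marks each recombined cell and its descendants with a fluorescent colour. Cells of the anterior prostate lobes were sorted by their Confetti colour 4 weeks after induction, and the size of the patches of each colour decided whether its cells counted as a dominant or a minor clone. The series title places the work in the immune control of clonal growth in early prostate cancer, and the comparison asks how cells of clones that took over large areas differ from cells of clones that stayed small. Bulk RNA-seq gave 5 libraries of dominant clones and 7 of minor clones, as TPM values (transcript abundances scaled to the same total in every library). Single-cell RNA-seq gave 1 library of each kind. The TPM table holds no read counts, so the depth of the bulk libraries is unknown. The dominant single-cell library had 8947 barcodes with 55601775 unique molecular identifiers (UMIs), and the minor library had 6860 barcodes with 50571553 UMIs. No label says whether the bulk libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. The tests treat all bulk libraries as independent, which no label states.

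Of the engineered genes, Kras and Pten did not pass the threshold between the groups, which does not show that their levels were equal. In the limma fit across all genes, Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239, GRCm38) stood at 111 ± 6.41 TPM (SD, n = 5) in dominant and 118 ± 12.5 TPM (n = 7) in minor libraries, a log2 fold change of -0.08 ± 0.10 (SE; adjusted p = 0.665). Pten (chromosome 19, 32757497 to 32826160), which opposes PI3K signalling, stood at 14.1 ± 2.27 TPM and 11.5 ± 2.09 TPM, a log2 fold change of 0.28 ± 0.17 (adjusted p = 0.311). Nkx3-1 (chromosome 14, 69190638 to 69194662), the prostate transcription factor whose locus carries the recombinase, lay between 0.0158 and 1.30 TPM in the dominant libraries and between 0.0300 and 2.39 TPM in the minor ones, too low to be tested. In epithelial cells of the single-cell libraries, 1 per group, the log2 ratio was 0.12 for Kras and 0.47 for Pten, with a median of 0.23 for all genes. Gene totals do not separate transcripts of recombined and unrecombined alleles.

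Macrophage genes were far more abundant in the dominant libraries. All 13 measured members of the macrophage and monocyte list rose, and 13 rose when adjusted over the list alone. The subunits of complement component C1q, which tissue macrophages produce, were among the largest rises. C1qc (chromosome 4, 136889804 to 136893065) had a log2 fold change of 4.79 ± 0.53 (SE, limma adjusted p = 0.000161). C1qa (136895917 to 136898803 on the same chromosome) stood at 738 ± 421 TPM (SD, n = 5) against 26.7 ± 13.7 TPM (n = 7), and C1qb at 1558 ± 851 TPM against 63.4 ± 31.1 TPM. The lysozyme gene Lyz2 (chromosome 10, 117277331 to 117282321) stood at 2563 ± 1222 TPM against 126 ± 63.8 TPM, and Adgre1, which encodes the macrophage surface protein F4/80, at 47.8 and 2.60 TPM. Every dominant library lay above every minor library for 12 of the 13 genes, Ccr2 being the exception with 4 of 5. The other genes among the 12 largest rises were Ms4a7, Ccl12, Aif1, Ly86, Cd72, Ms4a6c, Trem2 and Ccl8, with log2 fold changes from 3.87 to 4.67. Of these, Ccl8, a monocyte-attracting chemokine, exceeded all minor libraries in 3 of 5 dominant ones. The mean of the macrophage list differed by 3.45 on the log2 scale (7.85 ± 0.70 against 4.40 ± 0.62, SD; exact permutation p = 0.00126, the smallest that the 792 splits of the libraries can give; adjusted p = 0.0143). Camera gave the list an adjusted p of 1.64e-26, and an adjusted p = 0.0615 with an estimated correlation between genes.

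Other leukocyte genes rose alongside. In the pan-leukocyte list 8 of 9 genes rose (9 of 9 when adjusted over the list alone), among them Tyrobp, an adaptor of myeloid receptors (647 against 47.2 TPM), and Ptprc, which encodes the leukocyte antigen CD45 (28.2 against 4.41 TPM). Their list mean differed by 2.85 (exact permutation, adjusted p = 0.0143; camera adjusted p = 1.05e-16, and adjusted p = 0.0969 with an estimated correlation). Of 11 genes of MHC class II antigen presentation, 5 rose (9 when adjusted over the list alone), with Ctss, a lysosomal protease of antigen-presenting cells, at 1443 against 106 TPM and H2-Eb1, an MHC class II chain, at 1977 ± 969 against 433 ± 168 TPM. The list mean differed by 1.64 (exact permutation, adjusted p = 0.0258; camera adjusted p = 2.70e-11, and adjusted p = 0.272 with an estimated correlation). The dendritic cell list differed by 0.99 (adjusted p = 0.0258), with Itgax past the threshold (3 of 5 when adjusted over the list alone), and the neutrophil list by 0.91 (adjusted p = 0.0429), with S100a8 past it (6 of 9 when adjusted over the list alone), both by exact permutation. With an estimated correlation both lists had an adjusted p = 0.272, where camera with its preset correlation gave 0.00833 and 8.91e-05. Of the 12 measured T and NK cell genes none passed the threshold, and their mean differed by -0.03 (exact permutation, adjusted p = 0.973; camera adjusted p = 0.425). Among the B and plasma cell genes, 3 were measured, too few for a list test, and Ighm had 28.7 TPM in dominant against 3.84 TPM in minor libraries. Igkc (45.6 against 64.3 TPM, log2 fold change 1.26 ± 1.51, SE) and Jchain (4.14 against 8.72 TPM, 0.36 ± 1.04) did not pass, and their arithmetic means and log2 fold changes differ in sign.

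**Figure D1:**
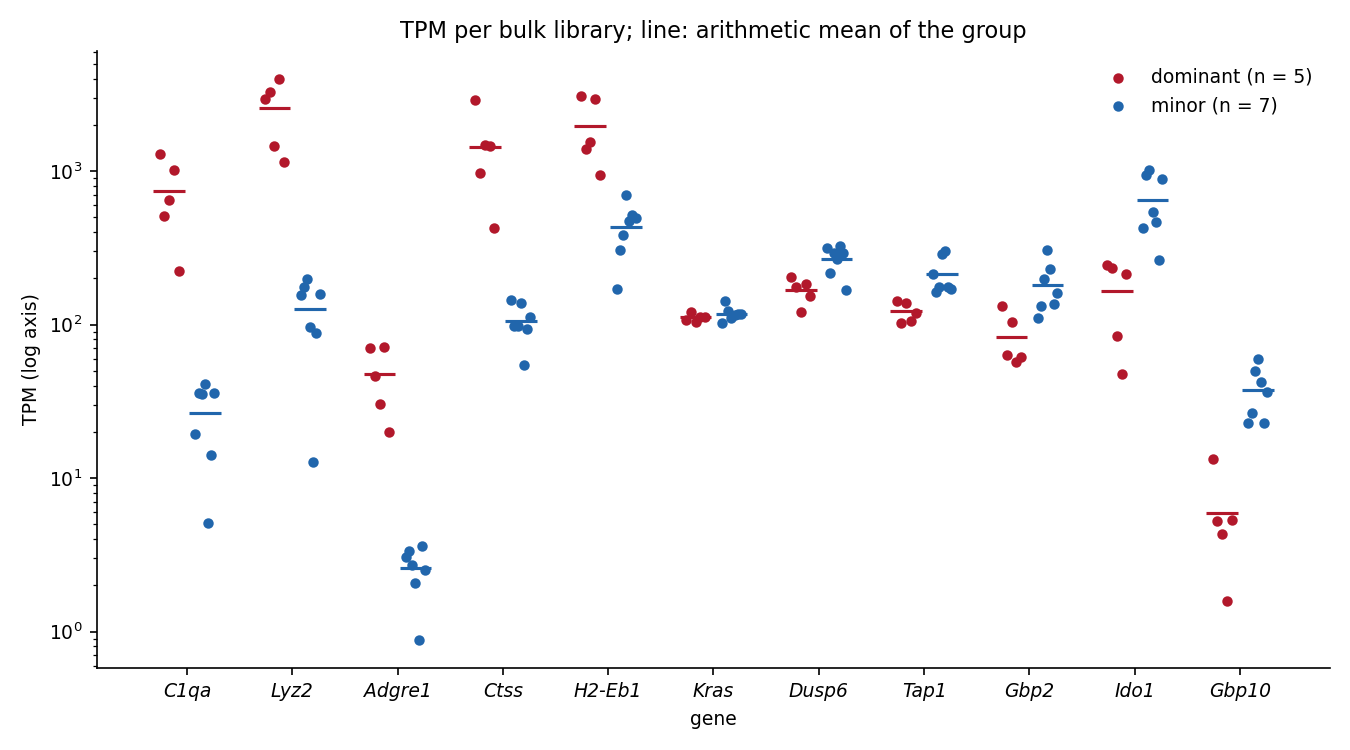
TPM of 11 genes (log axis) in each of the 5 dominant and 7 minor bulk libraries, a point per library and a line at the arithmetic mean of each group. For C1qa the dominant libraries lay between 225 and 1293 TPM and the minor ones between 5.11 and 40.9 TPM, for Ido1 between 47.3 and 243 TPM and between 264 and 1008 TPM, and for Kras the groups overlapped.

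Signalling and ligand genes of the immune lists moved both ways. Of 20 checkpoint and regulatory ligands, 6 rose (Cd86, Cd80, Vsir, Pdcd1lg2, Cd274 and Entpd1) and 3 fell (Ido1, Nectin2 and Cd276); 7 and 4 passed when adjusted over the list alone. Cd86, a costimulatory ligand of antigen-presenting cells, stood at 54.3 against 4.92 TPM. The chemokine and cytokine list had 5 risen genes of 25 (6 when adjusted over the list alone), with Ccl4 at 1034 against 150 TPM, besides Ccl8, Ccl3, Cxcl3 and Il18. In the list of NF-kappaB and inflammatory genes Cd14, Tlr2, Il1b and Sod2 rose and Rela, which encodes the NF-kappaB subunit p65, fell, of 23 measured (6 and 5 when adjusted over the list alone). Camera called these lists higher with adjusted p of 0.0259, 0.000855 and 0.0259, and with an estimated correlation the adjusted p were 0.319, 0.320 and 0.790. The list means did not pass the exact permutation test (adjusted p = 0.0702, 0.229 and 0.239). The median of the checkpoint list was -0.01 while its mean was 0.37.

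A group of interferon-inducible genes fell. Among the 12 largest falls were Gbp10 (chromosome 5, 105215699 to 105239533), Gbp4 and Gbp6, guanylate-binding GTPases of cell-autonomous immunity. The tryptophan-degrading enzyme Ido1 (chromosome 8, 24584136 to 24597009) and the chemokine gene Cxcl11 were also among them. GENCODE M21 types Cxcl11 as a polymorphic pseudogene, so whether its transcript gives a working T-cell-attracting chemokine in these mice is unknown. Gbp10 stood at 5.96 ± 4.39 TPM (SD, n = 5) against 37.3 ± 14.3 TPM (n = 7), a log2 fold change of -2.59 ± 0.37 (SE; adjusted p = 0.000662), and Ido1 at 165 ± 91.8 against 648 ± 292 TPM, a log2 fold change of -2.08 ± 0.44 (adjusted p = 0.0113). Every dominant library lay below every minor one for both, and both stayed past the threshold in every setting run. The other fallen genes named in this paragraph did not. Gbp4, Gbp6 and Gbp10 are neighbouring, related genes on chromosome 5, and how reads common to such relatives were assigned is not given in the sources used here. In the interferon response list 6 of 32 genes fell, namely Irgm1, Igtp, Gbp3, Gbp2, Irf1 and Iigp1, with log2 fold changes from -1.17 to -0.73, and Irf8, a transcription factor of myeloid cells, rose by 2.11; 8 fell and 1 rose when adjusted over the list alone. Others of the list had values near 0, such as Isg15 at 0.01 ± 0.26 (SE; adjusted p = 0.982). The list mean differed by -0.38 (exact permutation, adjusted p = 0.0702). Camera gave an adjusted p = 0.0259, and adjusted p = 0.804 with an estimated correlation. Without the 3 libraries richest in seminal vesicle transcripts camera placed the list in the opposite direction relative to the other genes (adjusted p = 0.601). The median of all genes was -0.31 in that setting, so this direction does not show that the list rose. Of 18 genes of MHC class I antigen presentation, the peptide transporters Tap1 (122 against 212 TPM) and Tap2 fell (5 when adjusted over the list alone), and the list mean differed by -0.35 (exact permutation, adjusted p = 0.0429; camera adjusted p = 0.0319, and adjusted p = 0.539 with an estimated correlation). When libraries were scaled to genes that mark the epithelial class of the single-cell data, the means of the interferon and MHC class I lists turned to 0.08 and 0.10.

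Genes that report on MAPK signalling, the pathway downstream of Kras, were lower in the dominant libraries. Of 20 measured MAPK targets 5 fell (7 when adjusted over the list alone): the phosphatases Dusp4, Dusp5 and Dusp6, which feed back on the pathway, the receptor Epha2 and the EGF receptor ligand Areg. None of these 5 stayed past the threshold in every setting run. Dusp6 stood at 167 ± 31.9 TPM (SD, n = 5) against 268 ± 56.4 TPM (n = 7). The list mean differed by -0.53 (4.60 ± 0.10 against 5.12 ± 0.19, SD; exact permutation p = 0.00126, the smallest possible; adjusted p = 0.0143; camera adjusted p = 0.00995, and adjusted p = 0.319 with an estimated correlation). The 230 measured genes that mark the epithelial class of the single-cell data had a median log2 fold change of -0.51, with quartiles of -0.72 and -0.16, and 43 of them fell and 0 rose. After scaling to these genes the MAPK list mean differed by -0.12. It differed by -0.38 with median-ratio scaling and by -0.45 with quantile normalization.

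Several further lists held fallen members. In the p53 and senescence list Plk2, Aen and Sesn2 fell (list mean -0.34, exact permutation, adjusted p = 0.0477; 7 fell and 1 rose when adjusted over the list alone), a mean that turned to 0.10 with scaling to epithelial genes. The Wnt and Notch list mean differed by -0.49 (exact permutation, adjusted p = 0.0429) with none of its 14 genes past the threshold, and it was -0.10 with that scaling. Camera in limma did not call either list (adjusted p = 0.238 and 0.0610). Fry in limma called the Wnt and Notch list (adjusted p = 0.0156) and not the p53 list (adjusted p = 0.0629). Myc and Klf4 fell in the AP-1 and immediate early list (exact permutation, adjusted p = 0.233 for the mean), Smad2 and Smad3 fell and Tgfbi and Id2 rose among TGF-beta and BMP genes (0.940), Inpp5d and Pik3cd rose and Foxo1 fell among PI3K/Akt/mTOR components (0.976), and Socs3 rose while Bcl6, Il13ra1 and Osmr fell among Jak/Stat genes (0.866). In the luminal list Cdh1, which encodes E-cadherin, and Krt18 fell (exact permutation, adjusted p = 0.251 for the mean), and Asns and Trib3 fell in the unfolded protein response list (0.175). Zeb2 rose by 2.03 in the epithelial-mesenchymal transition list (0.870), while it had 2.85 and 2.55 CPM in epithelial cells of the dominant and minor single-cell libraries. Whether the rises in these lists, those of Inpp5d and Pik3cd included, arose in epithelial cells or in leukocytes was not tested. In the glycolysis list Hk1 and Pfkl fell (0.199 for the mean; camera adjusted p = 0.0290, and adjusted p = 0.872 with an estimated correlation). The 32 oxidative phosphorylation genes had a mean difference of 0.12 and none passed the threshold (0.334 for the mean; camera adjusted p = 0.000662, and adjusted p = 0.749 with an estimated correlation). With scaling to epithelial genes the means of the AP-1, luminal, unfolded protein response and glycolysis lists turned to 0.20, 0.17, 0.13 and 0.07.

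No gene passed the threshold in the lists of the cell cycle (mean difference -0.35, exact permutation, adjusted p = 0.331), androgen receptor targets (-0.16, 0.700), basal epithelium (-0.38, 0.700), proximal luminal progenitors (-0.21, 0.237), complement and acute phase (-0.14, 0.885), heat shock and dissociation stress (-0.36, 0.239), fibroblasts (-0.46, 0.866), endothelium (-0.53, 0.597), smooth muscle and pericytes (-0.64, 0.597) or seminal vesicle epithelium (0.58, 0.866). With scaling to epithelial genes the negative means among these turned positive, except those of fibroblast, endothelial and smooth muscle genes. Among erythroid genes Alas2 rose, all 5 passed when adjusted over the list alone, and the list mean differed by 1.41 (exact permutation, adjusted p = 0.0751; camera adjusted p = 0.000282, and adjusted p = 0.319 with an estimated correlation). The calls of the exact permutation test for macrophage, pan-leukocyte and MAPK lists held without any single library. Those of the other 6 lists (MHC class II, MHC class I, dendritic cell, neutrophil, p53, and Wnt and Notch) ended without dominant replicate 1, 3 or 4, when 3 lists were called in place of 9, and some ended without other libraries. With 4 dominant libraries 330 splits remain and the smallest possible p is 0.00303, so a call can end with little change in the difference. Without dominant replicate 1, 3 or 4 the differences were 1.36, 1.57 and 1.53 for MHC class II (1.64 with all), -0.38, -0.39 and -0.32 for MHC class I (-0.35). They were 0.98, 1.11 and 1.15 for dendritic cells (0.99, with 4 in place of 5 genes) and 1.01, 0.97 and 0.70 for neutrophils (0.91). They were -0.28, -0.25 and -0.35 for p53 (-0.34) and -0.47, -0.41 and -0.52 for Wnt and Notch (-0.49). Mast cell, neuroendocrine and glial lists had 1 measured gene each and were not tested. Seminal vesicle genes took from 2.77 to 18170 TPM of a library and exceeded 5000 TPM in dominant replicates 2 and 4 and minor replicate 1.

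**Figure D2:**
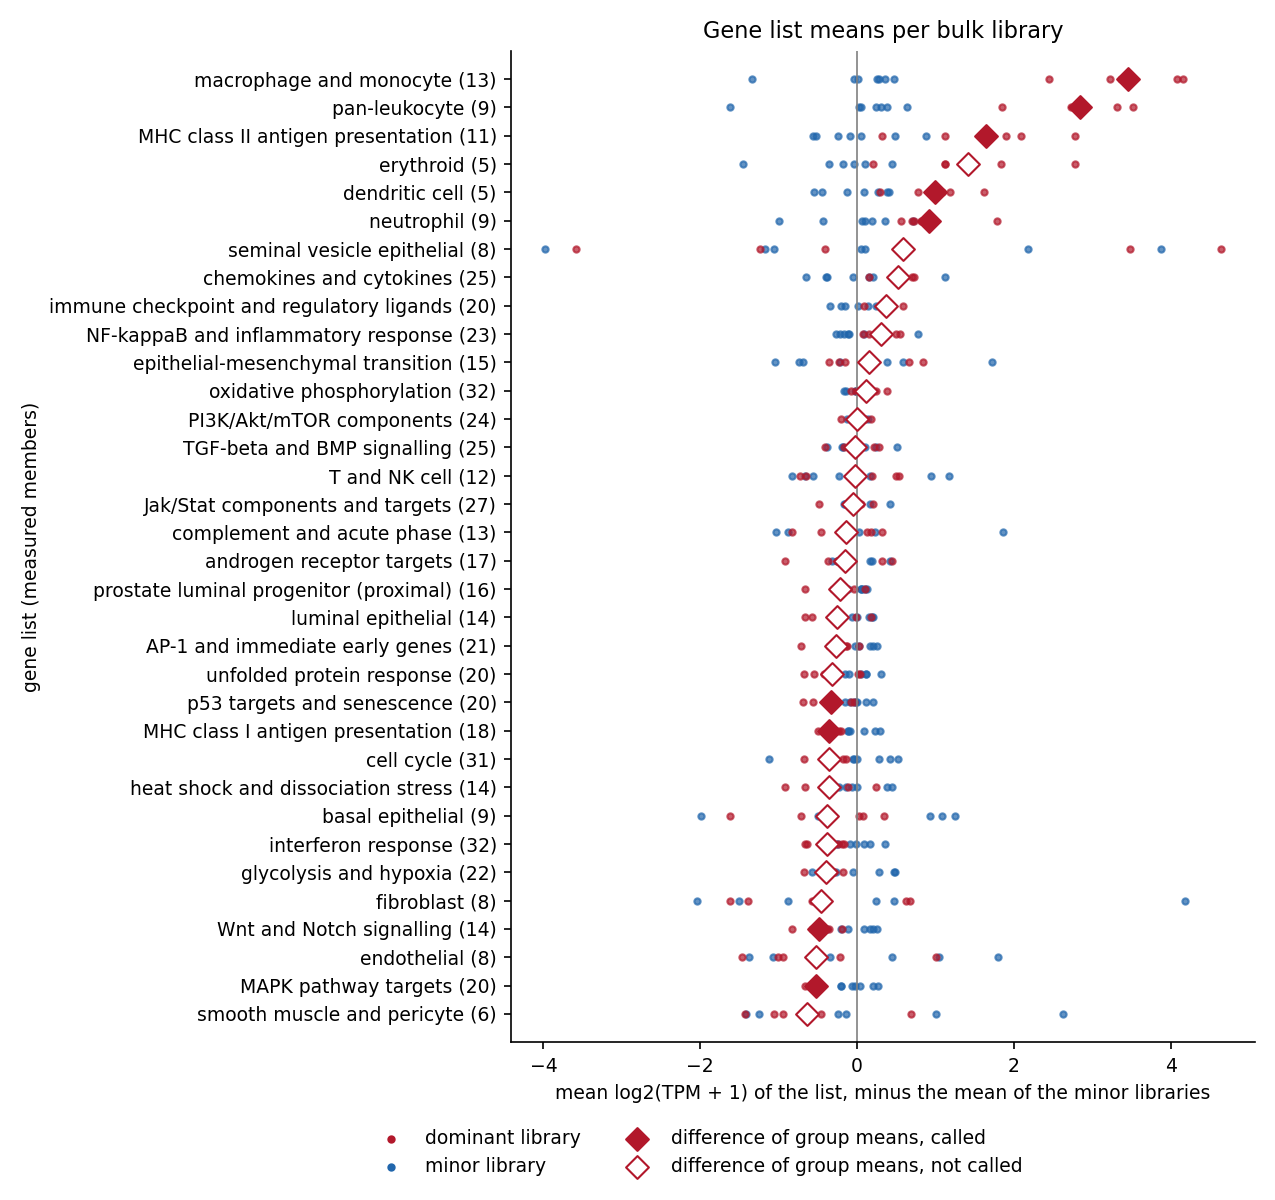
Difference between the mean of the 5 dominant and of the 7 minor bulk libraries for the mean log2(TPM + 1) of each of 34 gene lists (diamonds, filled where the exact permutation test passed after adjustment), with each library as a small point relative to the mean of the minor libraries. The macrophage list stood out at 3.45, followed by the pan-leukocyte list at 2.85, and the MAPK list lay at -0.53.

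Across all 12851 tested genes, limma called 1074 as changed, 492 higher and 582 lower in dominant libraries, with 3415 at an unadjusted p under 0.05. Of all tested genes, 631 had every dominant library above or below every minor one, where chance separates the groups for 0.253% of genes. The median log2 fold change of all genes was -0.19. The further genes among the 12 largest falls were Dennd6b, Apol6, Card10, Akap12, Trim15, Sema7a and Rsc1a1, with log2 fold changes from -1.69 to -1.42. Of the 492 higher genes, 232 (47.2%) belong to the 292 tested genes that mark the leukocyte class of the single-cell data, which make up 2.27% of tested genes. The split of higher against lower genes moved with scaling: 602 and 363 with quantile normalization, 613 and 285 with median ratios, and 1952 and 37 with scaling to epithelial genes, which shifted the median of all genes from -0.19 to -0.08, -0.05 and 0.22. Without dominant replicate 1, 3 or 4 the count was 525, 497 or 504, without minor replicate 4 or 5 it was 658 or 585, and with no filter on low values it was 675. Without single libraries the number of higher genes lay between 332 and 528, and that of lower genes moved more: it was 189, 143 or 172 without dominant replicate 1, 3 or 4, 376, 298, 259 or 206 without minor replicate 1, 3, 4 or 5, and 1039 or 877 without dominant replicate 2 or 5. Mitochondrial transcripts took 3.00 ± 0.52% of TPM in dominant and 2.03 ± 0.48% in minor libraries (SD; exact permutation p = 0.0114, adjusted p = 0.0455 over 4 quality measures), a call that ended without minor replicate 1, 3, 5, 6 or 7 or dominant replicate 2, 3 or 5 (adjusted p from 0.0606 to 0.0779). The difference of 0.977 percentage points lay between 0.816 and 1.12 without single libraries, where 330 or 462 splits remain in place of 792, so the ended calls do not show that it depends on a library. The number of genes at 1 TPM or more (exact permutation, adjusted p = 0.957), the share of TPM in the 50 most abundant genes (0.416) and the share in ribosomal protein genes (0.416) did not pass.

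Epithelial cells made up nearly all of both single-cell libraries, and leukocytes were a larger share of the dominant one. With 1 library per group there is no replicate check and no test, and the intervals given (95%, exact Clopper-Pearson for shares and exact Poisson for counts) cover counting error only. Of 8083 kept cells in the dominant library 97.2% (96.8 to 97.6%) were epithelial and 2.09% (1.79 to 2.43%) were leukocytes. Of 6078 kept cells in the minor library 97.6% (97.2 to 98.0%) were epithelial and 0.971% (0.740 to 1.25%) were leukocytes. Cells had been sorted by Confetti colour, which can set these shares. Fibroblast-like cells made up 0.260 and 0.362%, endothelial-like cells 0.124 and 0.0494% (3 cells in the minor library), and seminal vesicle-like cells 0.297 and 1.00%. A cluster of 7.18% of dominant and 2.96% of minor cells carried the smooth muscle genes Acta2, Myl9 and Tagln together with Epcam in 97.6% of its cells, and it is counted as epithelial. Within the leukocyte cluster, whose cells had a median of 4209 UMIs in the dominant and 2938 in the minor library, macrophage list genes took 51551 CPM (UMIs scaled to the same total) in the dominant library and 13754 in the minor one, while T and NK cell genes took 553 and 1687 CPM (458 and 523 UMIs), as shares of the UMIs of that cluster.

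Within epithelial cells of the single-cell libraries, genes of MHC class II antigen presentation were lower in the dominant library, opposite to the bulk libraries, where they were higher. The list had a median log2 ratio of -0.80, dominant over minor, against a median of 0.23 for all genes, and it lay at percentile 0 of 10000 random lists of matched expression. H2-Eb1 had 67.7 CPM (65.5 to 70.0) in dominant and 150 CPM (147 to 154) in minor epithelial cells, and H2-Aa had 75.1 and 142 CPM. In the leukocyte cluster the ratio of H2-Eb1 went the other way, at 1.29. Interferon response genes had a median of 0.07 (percentile 0.915, and 11.7 over all kept cells, leukocytes included). Ido1, at 59.1 CPM (57.0 to 61.2) against 133 CPM (130 to 136), and Gbp4, at 36.0 against 69.9 CPM, were lower there as they were in bulk. Cxcl9, an interferon-gamma-induced T-cell chemokine, had 102 and 271 CPM, and its bulk log2 fold change was -1.03 (limma, adjusted p = 0.337). Ido1, Cxcl9, Gbp2, Irf1 and Stat1 had a ratio below 0 in each of the 6 epithelial clusters, and H2-Eb1, H2-Aa and Gbp4 in 5 of them. Of further MHC class II genes, Cd74 was below 0 in all 6, Ctss and H2-DMb1 in 4, and Lgmn was above 0 in all 6. Cell cycle genes had a median of -0.16 (percentile 0), with 27 of 31 below 0, and unfolded protein response genes a median of 0.11 (percentile 2.69). The sums pool epithelial clusters whose shares differed. The mitotic cluster held 7.91% of dominant and 11.9% of minor epithelial cells, which can by itself lower cell cycle genes. H2-Aa, Cxcl9, Gbp4 and the other single-cell genes of this paragraph except Ido1 and H2-Eb1 were chosen after their values were seen.

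Lists at the other end were the epithelial-mesenchymal transition list, with a median log2 ratio of 0.54 (percentile 99.98), macrophage genes (1.07, percentile 99.99), basal genes (0.37, percentile 99.8), androgen receptor targets (0.36, percentile 99.3), TGF-beta and BMP genes (0.32, percentile 98.5), AP-1 genes (0.23, percentile 97.4), complement genes (0.38, percentile 97.3) and Wnt and Notch genes (0.34, percentile 97.2). The macrophage value is the median of 7 genes, most of them with few UMIs in epithelial cells: C1qa had 76 UMIs in 7859 dominant epithelial cells (median 5649 UMIs per cell), 1.48 CPM against 4359 CPM in the leukocyte cluster, a level that free RNA can give. The basal, AP-1 and macrophage lists stayed above the 95th percentile in every setting run. When cells with 10% or more mitochondrial UMIs were left out, the epithelial-mesenchymal list fell to percentile 92.6 and the complement list to 55.4. The complement list also fell to 94.0 with clustering on all shared genes, to 93.5 with the highest doublet scores removed, and to 86.1 and 86.7 without genes that the gene sets can affect, left out of the totals or of the lists alone. Androgen receptor targets fell to 89.5 with clustering on all shared genes and to 88.2 over all kept cells, and TGF-beta and BMP genes (93.8) and Wnt and Notch genes (94.1) fell below the 95th percentile without the cluster with smooth muscle genes, the latter also with the highest doublet scores removed (94.9). MAPK targets (0.11, percentile 5.78), MHC class I genes (0.05, 8.82) and the lists of oxidative phosphorylation (16.7), checkpoint ligands (18.7), p53 targets (25.9), glycolysis (27.2), heat shock (28.6), NF-kappaB (30.6), PI3K (38.8), luminal (41.8), Jak/Stat (50.8), chemokine (62.0) and proximal luminal progenitor genes (89.3) lay between the 5th and the 95th percentile. Of these, MAPK targets moved between 2.8 and 12.3 over the settings. Oxidative phosphorylation (2.6) and checkpoint ligands (4.45) fell below the 5th percentile when cells with 10% or more mitochondrial UMIs were left out. MHC class I genes (1) did so without the 50 most abundant genes. Proximal luminal progenitor genes rose to 98.7 without the cluster with smooth muscle genes, and chemokine genes to 99.8 over all kept cells. Epithelial cells of the libraries fell into the same 6 clusters in different proportions. A cluster led by Cck and Igfbp5 with the basal gene Trp63 held 28.1% of dominant and 19.8% of minor kept cells, a cluster led by Gsdmc3 and Lgals4 held 25.9 and 18.3%, and a cluster led by Csf2, Dynap and Crip1 held 1214 of the 8083 dominant and 1772 of the 6078 minor cells. List medians over all epithelial cells, those of the basal and epithelial-mesenchymal lists included, can thus reflect cluster shares. Whether list levels differed within clusters was not tested.

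The single-cell libraries had been counted against different gene sets, which limits single-gene ratios. The dominant library listed 55421 genes and the minor library 31053, of which 30726 were shared, and 3639 shared genes overlap or nearly match a gene counted in only 1 of the libraries. Among 3163 genes with at least 100 UMIs and 50 CPM, 63 had a ratio beyond 2-fold, 23 higher and 40 lower in the dominant library, and 40 of the 63 (63.5%) were such genes, against 23.4% of the 3163. Of the 12 largest ratios in each direction, 11 of the lower genes (AY036118, Rbm42, Sssca1, Ptp4a1, Slc39a7, Atp5g2, Fam173a, Ndufb4, Sec61g, Fam220a and Atp5l) and 5 of the higher ones (Atp6v0c, Timm23, Ctla2a, Spp1 and Gstp1) were such genes. AY036118 had 0 UMIs in the dominant library, which allows up to 0.0585 CPM (3 UMIs of the total), and 567 CPM in the minor one. The others were Nxf1 on the lower side and Ccdc85b, Ndfip1, Wdr33, Btg3, Pcna, Tagln and Mgp on the higher side. Nxf1 and the first 5 of these had ratios of one sign in all 6 epithelial clusters and bulk log2 fold changes between -0.33 and -0.03, so that differing gene models cannot be excluded for them. Tagln is also a leading gene of the cluster with smooth muscle genes.

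**Figure D3:**
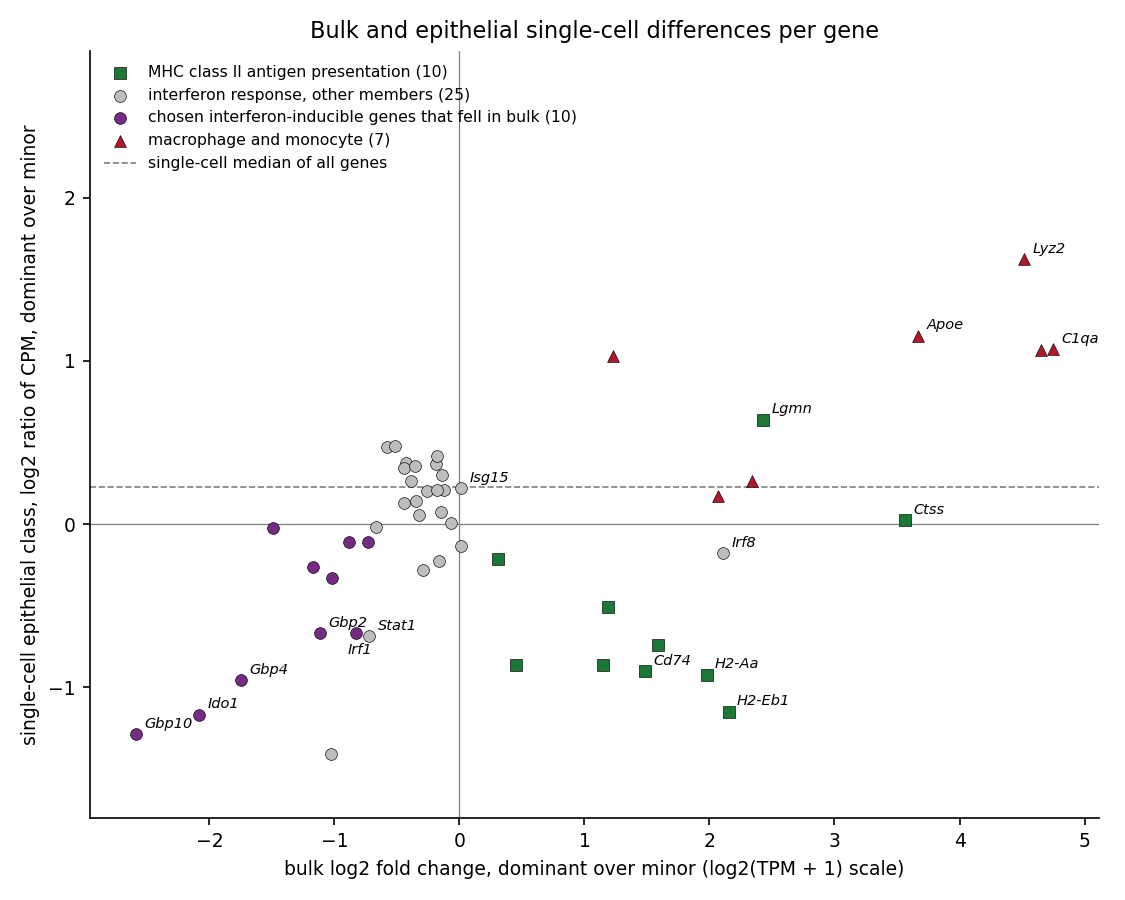
Bulk log2 fold change (horizontal) against the single-cell log2 ratio of CPM in epithelial cells (vertical), both dominant over minor, a point per gene, with the single-cell median of all genes as a dashed line at 0.23. The 10 interferon-inducible genes shown were chosen from the fallen members of the interferon response list and the 12 largest falls, so other fallen genes of this kind (Ubd, Tap1 and Tap2 among them) are not marked. These 10 and 9 of 10 MHC class II genes lie below that line, the latter with higher values in the bulk libraries.

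Over all genes, the direction of bulk and single-cell differences matched less often than not. Of 759 genes past the bulk threshold with a single-cell value, 37.0% had the same sign in both, against 33.1% of all 11198 genes measured in both, since most bulk values were below 0 and most single-cell ratios above 0. After the median of all genes was subtracted on each side, 66.9% of the called genes matched, against 53.7% of all genes. Among called genes that rose, 78.2% had the same sign, against 79.7% of all genes with a bulk value above 0, and among called genes that fell 22.6% did, against 15.2% of all genes with a bulk value below 0. Of the 50 genes with the smallest bulk p, 76% matched after the medians were subtracted.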

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

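The tests of explanations in this part were chosen after the results they address had been seen, and each pattern is a hypothesis tested on the data in which it was found.

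Macrophage genes were higher in every dominant bulk library than in any minor one for 12 of 13 genes. Of the 221 tested leukocyte-class genes on no fixed list and outside the largest changes, 183 were higher, 23.35 times their share of such genes tested, which is consistent with macrophages, or their RNA, among the cells sorted from dominant clones, although this class is itself rich in macrophage transcripts. A lower purity that brings in fibroblasts, endothelial, smooth muscle and T cells as much as macrophages is argued against. The upper 95% bounds of these list differences reached at most 1.594, below the lower bound of 2.551 of the macrophage list. The erythroid, dendritic cell and neutrophil lists, with differences of 1.41, 0.99 and 0.91, were not part of this test, so it does not cover other cell types. Expression by the epithelial cells is argued against for most of the 13 genes by a median epithelial level of 0.03671% of the leukocyte level in the dominant single-cell library. It stays open for Apoe, Cd14, Mrc1 and Cd68, at 2.08 to 6.40%. There the epithelial cells, being far more numerous, held more of the UMIs than the leukocyte cluster (Apoe 32868 and 25577, Cd14 5416 and 1367). Whether dominant patches held more macrophages in the tissue, or more of them passed the sort by colour, which is meant to exclude cells without the Confetti label, cannot be separated with these samples.

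Interferon-inducible genes (Ido1, Cxcl11, Irf1, Gbp2, Gbp3, Gbp4, Gbp6, Gbp10, Igtp, Iigp1 and Irgm1) were lower in the dominant bulk libraries. Dilution by leukocyte RNA stays open: after each library was scaled to epithelial genes, the mean difference of the 11 genes was -0.94 with an upper 95% bound of -0.1709, but they were chosen because they fell in these libraries, and the fixed list of 32 interferon response genes then differed by 0.08 (-0.30 to 0.45). In the epithelial single-cell sums the median log2 ratio of the 10 measured genes was -0.4994, at percentile 0 of matched random lists, which is consistent with a lower response in the epithelial cells of dominant clones. These single-cell libraries are 1 per group, and their cells may differ in ways other than the clone's size.

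MAPK target genes had a list mean that differed by -0.53 between the bulk groups. After scaling to epithelial genes the difference was -0.12 with an upper 95% bound of 0.06642, so a dilution of epithelial RNA by leukocyte RNA could account for it. That scaling removes any change that the list shares with the epithelial genes, whatever its cause. It therefore cannot tell dilution from a lower level in the epithelial cells. The difference was -0.38 with median-ratio scaling and -0.45 with quantile normalization. In the epithelial single-cell sums the list lay at percentile 5.78, between the bounds set for a lower and an unchanged level, so a lower level in the epithelial cells cannot be told apart from none. The alternatives put the list between 2.8 (all kept cells) and 12.3 (without the cluster with smooth muscle markers), on both sides of the lower bound, and a new draw of random lists for the same cells (doublet calls kept) gave 4.

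Of 100 splits of the 12 libraries into 5 and 7, the real one included, 2 gave as many changed genes as the real split (1074, against 1092 in the highest other split), a share under the threshold of 0.05 set for excluding chance. The splits treat all libraries as exchangeable, while residuals of pairs of libraries correlated at up to 0.59. A chance alignment with such structure among the libraries is therefore not excluded. The 100 splits are a part of the 792 possible ones. That other split mixed the groups, with 3 dominant libraries among its 5. A grouping other than dominant against minor thus changed as many genes, and the number alone does not tie the changes to clone size. For the number of lists called by camera, 46 of 100 splits gave as many as the real 14 (25 in the highest other split), so chance cannot be excluded for that number.

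Single libraries stood apart from the rest of their group in 14 of 128 groups of values, of which chance gives about 5%, as log2(TPM + 1). Minor replicate 5 had the lowest macrophage list mean (3.061, the next library 4.364) and the lowest pan-leukocyte mean (2.466), with C1qc at 2.582, C1qb at 3.505, Lyz2 at 3.788, Ly86 at 0.7239, Cd72 at 1.155 and Ms4a6c at 0.5317. Minor replicate 7 had the highest NF-kappaB mean (7.015) and the highest fibroblast mean (8.492, the next library 4.782). Minor replicate 2 had the lowest cell cycle mean (3.294). Dominant replicate 4 had the highest neutrophil mean (4.308). Dominant replicate 3 had the lowest Pten level (3.491), and dominant replicate 2 had the highest Rsc1a1 level (2.311). Genes counted only in the dominant single-cell library took 4.381% of its UMIs, and genes counted only in the minor one took 0.041% of the UMIs there.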

How the results depend on the processing

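Settings chosen after seeing the data were scaling to epithelial genes, leaving out leukocyte genes, leaving out libraries high in seminal vesicle genes, clustering on all shared genes, removing the highest doublet scores, and those on the gene sets, the cluster with smooth muscle markers and the bulk and single-cell direction other than the sets of smallest p. Where no construction of the setting shows it, the cause was not tested.

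Of the 102 named genes past the bulk threshold, 47 stayed past it in every setting run, 0 reversed, and 449 of 2493 values were weaker. The only falls among the 47 were Gbp10, Ido1, Akap12, Card10, Sema7a and Smad3. Other falls among the 102, such as Dusp6, Tap1, Irf1, Cdh1 and Myc, did not pass in some settings. Scaling to epithelial genes left 37 lower genes in all. The number of changed bulk genes (1074) was 675 with no filter on low values (25040 genes tested), 1989 when scaled to epithelial genes, 658 without leukocyte genes (fewer genes tested) and 604 without libraries high in seminal vesicle genes (fewer libraries), and from 497 to 1543 without single libraries, below the main count by over 1.5 times without dominant replicate 1 (525), 3 (497) or 4 (504) or minor replicate 4 (658) or 5 (585). With the replicate number as a block (replicate block) it was 857, and 15 lists were called. The labels do not state that numbers pair libraries: the residuals of 5 pairs of the same number correlated between -0.33 and 0.54, and 0 of the dominant libraries correlated best with its own number. Titles also carry serial numbers, which place some libraries of both groups side by side. Among such neighbours, residuals correlated at 0.59 for minor 2 and 3, 0.59 for minor 4 and 5, and 0.56 for dominant 2 and minor 3. Dominant 1 correlated best with minor 4 (0.37) and dominant 5 with minor 2 (0.21), which are not neighbours. A block by serial number was not tested, so matched libraries cannot be excluded.

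The number of lists called by camera (14) was 8 at a TPM of at least 5, 8 with median-ratio scaling, 8 when scaled to epithelial genes, 5 without leukocyte genes, 9 without libraries high in seminal vesicle genes, 0 with an estimated correlation and 7 with fry, and from 10 to 16 without single libraries. Fry called the macrophage, pan-leukocyte, dendritic cell, MHC class II, MHC class I, MAPK, and Wnt and Notch lists. The interferon response list turned to the opposite direction relative to the other genes without libraries high in seminal vesicle genes (adjusted p = 0.601, camera in limma). The median of all genes was -0.31 in that setting. The exact permutation test of list means called from 3 to 11 lists without single libraries (9 with all), with 3 without dominant replicate 1, 3 or 4, 5 without dominant replicate 5, and 4 without minor replicate 2 or 3. Of the quality measures 0 to 1 were called without single libraries.

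The epithelial share of the dominant single-cell library was 96.75% with at least 200 genes and a mitochondrial share under 30%, 97.74% with a mitochondrial share under 10% and 97.65% with the highest doublet scores removed. That of the minor library was 98.38% with a mitochondrial share under 10%, 98.4% with clustering on all shared genes and 98.27% with the highest doublet scores removed. Leukocyte shares were 2.832 and 1.379% with at least 200 genes and a mitochondrial share under 30%. Epithelial genes beyond 2-fold numbered 36 without genes that the gene sets can affect. This setting has fewer genes and also leaves them out of the CPM totals, which moved the median ratio of all genes from 0.23 to 0.09. The AP-1 list, whose median and that of all genes both stood at 0.23, turned to -0.007011 relative to all genes in that setting, a shift about 0 (percentile 96.55, before 97.4). Bulk and single-cell directions matched for 80% of the 50 genes with the smallest p (79.7% of all genes with a bulk value above 0 match), 43% of 500, 30.56% without leukocyte genes and 66.93% after median centring. The bulk depth is unknown, and the single-cell depth limits values to genes with at least 100 UMIs.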

Other observations

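Genes and contrasts in this part were chosen after their values had been seen, and none was tested between groups, since each single-cell group has 1 library. Within epithelial cells, members of the interferon response list and related genes did not all have ratios of the same sign. Stat1, Irf1, Gbp2, Ido1, Cxcl9 and the MHC class II invariant chain gene Cd74 had log2 ratios below 0 in all 6 epithelial clusters. Cd74 stood at 429 CPM in the dominant and 801 CPM in the minor library, and Ubd, an interferon-gamma-induced ubiquitin-like modifier, at 138 and 241 CPM. Irf7, Irf9, Usp18, Rtp4, Ifit1 and Bst2 had ratios above 0 in all 6 clusters, with cluster values from 0.03 for Bst2 to 0.54 for Usp18, around the median of all genes of 0.23. In the bulk libraries none of Irf7, Irf9, Usp18, Rtp4, Ifit1 and Bst2 passed the threshold in limma (adjusted p from 0.156 for Irf9 to 0.758 for Ifit1).

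The composition of the leukocyte cluster differed as well. Lyz2 took 7187 CPM of the leukocyte UMIs in the dominant library and 1977 CPM in the minor one, and Apoe took 30892 and 8078 CPM. The T cell genes Cd3d, Cd8b1 and Nkg7 took 54.4, 15.7 and 55.6 CPM in the dominant library and 181, 155 and 232 CPM in the minor one, from 45, 13 and 46 UMIs and 56, 48 and 72 UMIs. Over all kept cells, macrophage list genes took 1571 CPM in the dominant and 486 CPM in the minor library, a log2 ratio of 1.69. T and NK cell genes took 33.2 and 26.0 CPM over all kept cells, most of it from Trbc2 outside the leukocyte cluster, and without Trbc2 they took 9.49 and 10.7 CPM (499 and 529 UMIs). CPM within the leukocyte cluster are shares of its own UMIs, so they fall for other genes where macrophage genes take more. A cluster led by mitotic genes such as Nusap1, Aspm and Cenpf held 7.91% (7.33 to 8.53%) of dominant and 11.9% (11.1 to 12.7%) of minor epithelial cells.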
